A study of Rattus norvegicus with 125 samples.

How the data were processed

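RNA sequencing values of microdissected rat kidney tubule segments, glomeruli and cortical collecting ducts were used as deposited, in RPKM (reads per kilobase of transcript model, scaled to the reads of the library), computed by the authors per RefSeq transcript. The kidneys came from male Sprague-Dawley rats, of 200 to 250 g for the segments. The submitters' processing notes name Trimmomatic 0.32, STAR 2.3.0-r192, SAMtools, HOMER and the genome build rn5; the order and settings of these tools are not given in the sources used here. Libraries followed a single-cell protocol with paired 50 nt reads. The deposited data hold 2 RPKM tables of the segments and glomeruli, made with and without polyadenylation-site data, and 1 RPKM table of the water-load experiment. How the polyadenylation-site data entered the first table is not given in the sources used here. The first was the main table and the other an alternative. No reference genome was used, so no positions are given.

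Each segment table has 17974 transcript entries and that of the water-load experiment 17975, of which 1 has no symbol. They give 17144 gene symbols; for 503 with more than 1 transcript, the transcript with the highest mean was kept. Of the main table's entries, 9 have no glomerulus value. Libraries of tubules correlated between the 2 segment tables at 0.917 to 0.968 (across genes, which are not independent replicates), but glomeruli at 0.0086 to 0.0137, because the glomerulus columns of the second table are displaced by up to 67 entries. That table was therefore not used for glomeruli. Of 9594 genes with a mean of at least 1 RPKM in a table, 5074 were within 1.1-fold between the tables and 379 differed by over 4-fold.

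The files give no counts, so limits from counting are unknown. Relative depth was estimated from the whole-number ratios that low RPKM values form between libraries, with 5 reference libraries and a tolerance of 0.0002 on the log2 scale; at least 3 of 5 references gave the same value in 117 libraries.

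Groups follow the labels. Values were taken as log2(RPKM + 1), and genes with at least 1 RPKM in at least 4 libraries of a fit were tested with the trended moderated test of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within a comparison. Fold and log2 changes are on this scale and are the second group minus the first. All 14 segments shared 1 fit of 105 libraries, joined by the 5 glomeruli for Glomerulus against S1. A gene was called at an adjusted p under 0.05 and an absolute log2 change of at least 1, without the limit on change for water load, whose 8 libraries had a fit of their own. A gene was selective for a segment when its mean exceeded that of each of the other 13 by at least 1 and the largest of the 13 p-values, adjusted over genes, was under 0.05. Aqp2 under water load was tested by exact permutation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

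The 36 gene lists, with 574 memberships of which 555 were in the table, and the rule for named genes were fixed before the data were examined, as were the groups, the tests and most alternative settings. Lists with at least 5 tested genes were tested with camera of limma, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. For water load fry, a second list test of limma, was also planned. Per comparison the rule names the 5 genes with the largest change in each direction among called genes whose libraries do not overlap, and members of the assigned lists; the text gives a part of these. Some genes are not reported here. For selective genes it names up to 3 per segment, and for water load Aqp2, list members and the 10 called genes with the smallest p in each direction. Genes outside the rule are said to be chosen after their values were seen. Replicate numbers were taken to pair libraries where residuals of every pair with the same number correlated above 0.1. Only those of the water-load experiment did. Single pairs still reached 0.724 in S1 against S2, 0.329 in mTAL against cTAL and 0.309 in CCD against OMCD. The medians over pairs there were 0.005, 0.022 and 0.016, so pairing of some segment libraries cannot be excluded.

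Fixed beforehand as alternative settings were a pseudocount of 0.1, no filter, quantile normalization, the second table, the replicate number as a block, both groups fitted alone, leaving out single libraries of groups of 4 or 5, and array quality weights for water load. Chosen after seeing the data were all transcripts, the log2 number of detected genes as a covariate, leaving out the 14 tubule libraries with fewer than 2500 genes (91 kept), and, for glomeruli, only genes within 4-fold between the tables. The last rests on tubule values, so it leaves in genes whose glomerulus values alone are off. Group labels were also redrawn in up to 100 splits per comparison. Tested on simulated data, a log2 change of 4 was recovered in 80.3% of genes for S1 against S2, 59.1% for LDLIM against tAL and 95.5% for water load. A change of 1 was recovered in 4.5%, 1.5% and 4.5%. Simulated values were normal around each gene's overall mean with its residual SD, without the lower bound of RPKM values. Groups differed only in the changed genes, so these shares may differ in the real data. The 7 polyadenylation-site samples were left out, since the tables used have no columns for them.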

Results

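RNA was sequenced from single tubule segments and glomeruli dissected by hand from collagenase-digested kidneys of male Sprague-Dawley rats. Of the 125 samples, 105 are libraries of 14 tubule segments, 5 are glomerulus libraries and 8 are cortical collecting duct libraries of a separate water-load experiment. The other 7 samples, whole kidneys sequenced at polyadenylation sites, are not analysed here. The proximal tubule is represented by S1, S2 and S3 (n = 7 each). Thin limbs are represented by the descending limb of short loops (SDL, n = 10), that of long loops in the outer medulla (LDLOM, n = 9) and in the inner medulla (LDLIM, n = 4), and the thin ascending limb (tAL, n = 7). Then come the medullary and cortical thick ascending limb (mTAL and cTAL, n = 7 each), the distal convoluted tubule (DCT, n = 8) and the connecting tubule (CNT, n = 6). The collecting duct is represented by its cortical (CCD, n = 11), outer medullary (OMCD, n = 7) and inner medullary (IMCD, n = 8) parts. The labels number the replicates of a segment but do not say whether they came from different rats, so the p-values measure the spread between these libraries, which may be technical.

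The number of genes at 1 RPKM (reads per kilobase of transcript, scaled to the library's reads) or more ranged from 1438 to 8574 of 17144 symbols among the tubule libraries. Segment medians ran from 2870 genes in mTAL to 6749 in CCD. Glomeruli had a median of 9298 genes and the water-load experiment medians of 8224.5 in controls and 8309.5 with water load. The tables hold no read counts. Depth relative to a common reference, recovered from whole-number ratios between low values, spanned 23.8-fold among tubule libraries, from 0.092 to 2.191. It is uncertain by small whole-number factors, since all 5 references gave the same depth for only 64 libraries, so no counting intervals are given.

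**Figure D1:**
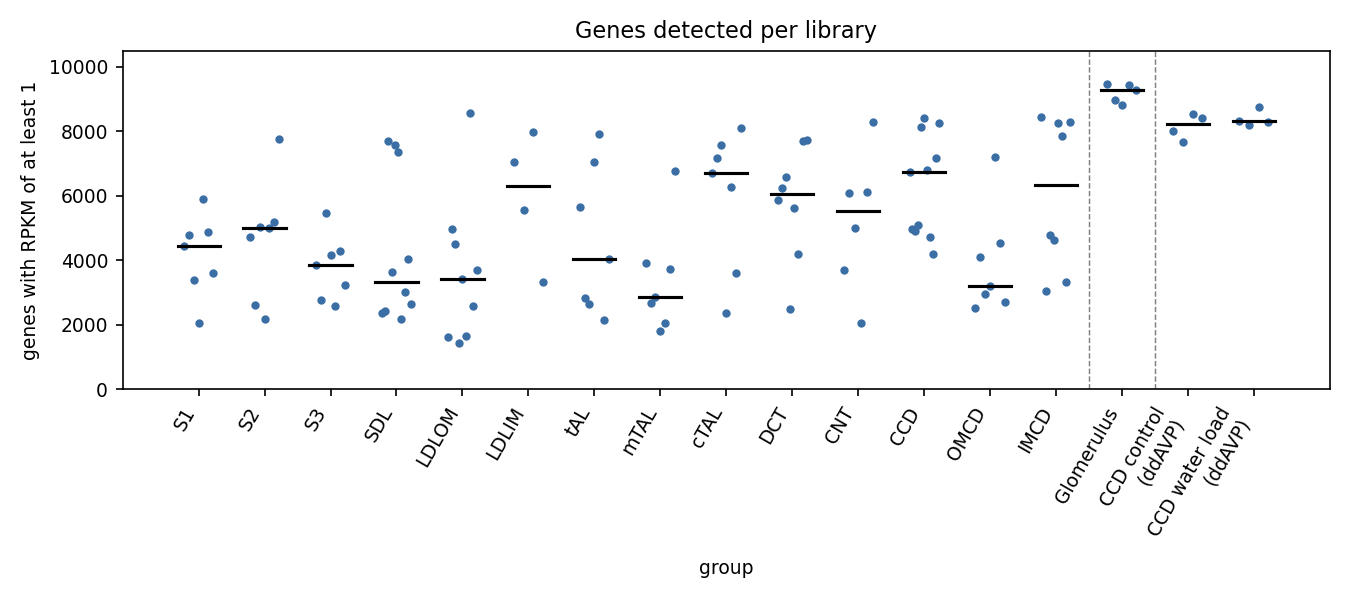
Genes with an RPKM of at least 1 (vertical axis, number of genes) in each library (points) of each group (horizontal axis), with the group median as a bar. The glomeruli, at 8818 to 9483 genes, lie above all 105 tubule libraries, which reach 8574.

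Slc34a1, the sodium phosphate cotransporter, averaged 1504 ± 2115 RPKM (SD, n = 7) in S1 and 1945 ± 2131 (n = 7) in S2. Slc12a1, the furosemide-sensitive cotransporter, averaged 336 ± 112 RPKM in mTAL and 368 ± 386 in cTAL (n = 7 each). Umod, the urinary glycoprotein uromodulin, reached 10710 ± 5978 RPKM in cTAL. Slc12a3, the thiazide-sensitive cotransporter, averaged 267 ± 122 RPKM in DCT (n = 8). Aqp2, the vasopressin-regulated water channel, averaged 4680 ± 3518 RPKM in CNT (n = 6), 7683 ± 4183 in CCD (n = 11), 7663 ± 7550 in OMCD (n = 7) and 8180 ± 5115 in IMCD (n = 8). Aqp1, the constitutive water channel, was highest in LDLIM at 3629 ± 1467 RPKM (n = 4).

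**Figure D2:**
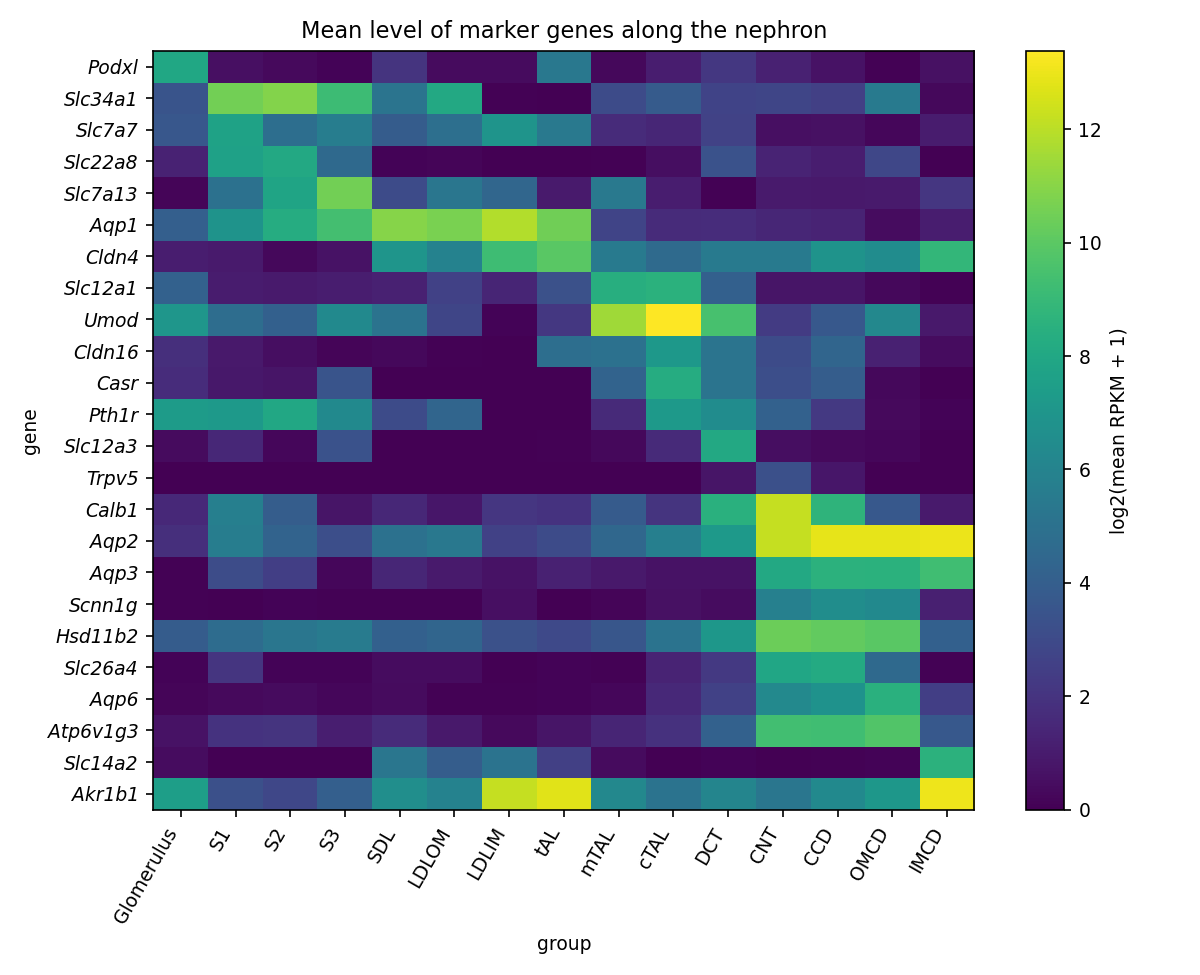
Mean level of marker genes (vertical axis) in the glomerulus and the 14 tubule segments (horizontal axis), as the log2 of the mean RPKM plus 1 (colour scale). Slc12a3 stands out in DCT, with a mean of 267 RPKM, and Slc14a2 in IMCD, with a mean of 388 RPKM.

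Genes that mark a single segment were sought against each of the other 13 segments. Slc12a3 was selective for DCT, where its level exceeded that in cTAL, the next highest, by 6.61 on the log2 scale (267 ± 122 against 1.97 ± 2.23 RPKM; adjusted p = 8.0e-22). S100a4, a calcium-binding protein, was selective for IMCD (6411 ± 4334 RPKM, against 123 ± 177 in LDLIM). So were Gpha2, a glycoprotein hormone subunit (533 ± 271 RPKM), and the aldo-keto reductase Akr1b8 (612 ± 527 RPKM). Selective genes of the proximal tubule included Cyp24a1, the vitamin D hydroxylase, in S2 (20.6 ± 22.5 RPKM) and Gc, the vitamin D binding protein, in S3 (84.2 ± 136 RPKM). Cxcl1, a chemokine, was selective for LDLIM (507 ± 320 RPKM) and Igf1 for mTAL (14.4 ± 15.2 RPKM). Further ones were the cyclooxygenase Ptgs2 for cTAL (49.0 ± 86.4 RPKM), the calcium channel Trpv5 for CNT (8.52 ± 10.2 RPKM) and the nucleotide receptor P2ry14 for OMCD (175 ± 82.7 RPKM). In all, limma called 132 of 11078 genes selective: 67 for IMCD, 14 for DCT, 13 for S3, 11 for LDLIM, 10 for S1 and 6 for cTAL. A further 4 marked S2, 3 tAL, 2 CNT, 1 mTAL and 1 OMCD, and 0 each were found for SDL, LDLOM and CCD. Trpv5, P2ry14 and S100a4 lost the call with a pseudocount of 0.1, Trpv5 also in the second table, and Ptgs2 and P2ry14 lost it without the 14 libraries under 2500 genes. On simulated data, 34 of 100 genes raised by 4 on the log2 scale were recovered, so many selective genes may be missed. The simulated values had no lower bound and no other differences between segments, so that share may differ in the real data.

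S1 and S2 ask how the early and middle proximal tubule differ (n = 7 each). Slc38a3, a glutamine transporter, rose from 1.78 ± 4.12 RPKM in S1 to 90.8 ± 85.9 in S2, by 4.73 ± 0.87 (SE) on the log2 scale (adjusted p = 0.00039). Slc7a7, an exchanger of cationic amino acids, was lower in S2, at 28.0 ± 31.0 against 208 ± 128 RPKM (log2 change -4.20 ± 1.00; adjusted p = 0.015). Of 15 tested genes of xenobiotic metabolism 5 rose and 0 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 2.3e-23, and adjusted p = 2.1e-06 with an estimated correlation). Among them was the fatty acid hydroxylase Cyp4a2, from 32.5 ± 43.4 to 284 ± 276 RPKM. The Cyp4a genes are close paralogs, and how reads were shared between them is uncertain. Of 12 organic ion transporters 3 rose and 0 fell, the same counts as when adjusted over the list alone (camera adjusted p = 2.5e-08, and adjusted p = 0.0060 with an estimated correlation). They included the cation transporter Slc22a2, from 22.5 ± 20.8 to 148 ± 103 RPKM, and the urate transporter Slc22a12, from 6.59 ± 10.8 to 70.3 ± 80.4 RPKM. Amino acid transporters moved both ways, with 3 of 14 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.103). By limma, 66 of 11078 genes passed, 51 higher and 15 lower in S2. Of the 66, 0 had libraries without overlap. The count was 38 with a pseudocount of 0.1, 37 without the libraries under 2500 genes and 6 with both groups fitted alone. That last fit ended the calls of Cyp4a2, Slc22a2, Slc22a12 and Slc7a7. The pseudocount ended those of Cyp4a2, Slc22a2 and Slc7a7, and leaving out the libraries under 2500 genes those of Slc22a2 and Slc7a7.

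S2 and S3 compare the middle and the late proximal tubule (n = 7 each). Slc4a4, a bicarbonate cotransporter, fell from 23.1 ± 25.7 RPKM in S2 to 0.0044 ± 0.0096 in S3 (log2 change -3.68 ± 0.525; adjusted p = 2.4e-07), with every S2 library above every S3 library. Slc7a13, an apical amino acid transporter, rose from 222 ± 268 to 1458 ± 1135 RPKM (log2 change 3.78 ± 1.01; adjusted p = 0.038), a call lost with a pseudocount of 0.1 and without the libraries under 2500 genes. Of 20 genes of proximal reabsorption 4 fell and 0 rose, and 7 fell when adjusted over the list alone (camera adjusted p = 2.5e-10, and adjusted p = 0.00056 with an estimated correlation). The gluconeogenesis list fell in 2 of 8 genes, 3 when adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.027 with an estimated correlation). Gatm, an enzyme of creatine synthesis, fell from 1815 ± 1959 to 139 ± 154 RPKM and G6pc, the phosphatase that releases glucose, from 156 ± 264 to 3.90 ± 4.34 RPKM. Organic ion transporters split, 2 of 12 higher and 2 lower, or 3 and 3 when adjusted over the list alone. The organic anion transporter Slc22a8 fell from 268 ± 278 to 23.1 ± 39.3 RPKM, and Slc22a13 rose from 1.31 ± 3.27 to 12.8 ± 16.8 RPKM. Leukocyte markers were lower in S3 (1 of 12 genes, 5 when adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.038 with an estimated correlation). C1qb, a complement subunit of macrophages, was at 0.0489 ± 0.0976 against 84.3 ± 124 RPKM. Immediate early and heat shock genes, with 0 of 16 called, were higher as a set (camera adjusted p = 0.0034), but not with an estimated correlation (adjusted p = 0.36). In total 98 genes passed, 25 higher and 73 lower in S3, of which 6 did not overlap (0.0583% of all tested genes by chance). That share counts genes called or not, so it cannot be set against the 6 called genes. The median of all genes moved by -0.11. Quantile normalization gave 112 genes with 35.7% higher. With S2 and S3 fitted alone 10 genes passed, and the calls of Slc4a4, Slc22a8, G6pc, Slc22a13 and C1qb ended. Those of Gatm and G6pc ended with a pseudocount of 0.1.

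SDL and LDLOM are descending thin limbs of short and long loops that run through the same zone (n = 10 and n = 9). Cldn3, a sealing tight junction protein, was lower in LDLOM, at 44.8 ± 127 against 244 ± 356 RPKM (log2 change -4.75 ± 1.08; adjusted p = 0.023). Of 17 claudins 1 was lower and 0 higher, or 3 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.49). In the thin limb list the only call of 14 genes was again Cldn3 (camera adjusted p = 0.92). The caveolar protein Cav1 (207 ± 268 against 1.57 ± 2.77 RPKM), the transcriptional inhibitor Id1 (539 ± 433 against 67.4 ± 103 RPKM) and the cytochrome P450 gene Cyp4b1 (102 ± 132 against 0.0635 ± 0.120 RPKM) were also lower in LDLOM. Vstm2b was higher (13.3 ± 23.7 against 0.844 ± 2.60 RPKM). These 4 genes were chosen after their values were seen. Leukocyte markers, with 0 of 12 called and 2 lower when adjusted over the list alone, were lower in LDLOM as a set (camera adjusted p = 0.015), but not with an estimated correlation (adjusted p = 0.77). Altogether 17 genes passed, 16 lower and 1 higher, 0 of them without overlap, while the median of all genes moved by -0.23. Quantile normalization gave 21 genes with 47.6% higher and ended the calls of Cldn3, Cav1 and Id1; with the covariate 30.4% were higher. Fitted alone, these 2 groups gave 1 gene, which was not among the 17, so all 17 calls ended. A pseudocount of 0.1 gave 10 and ended the calls of Cav1, Id1 and Vstm2b. Without libraries under 2500 genes those of Cldn3, Cav1 and Id1 ended, without the filter those of Cav1 and Vstm2b, and in the second table that of Id1.

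LDLOM and LDLIM follow the long-loop descending limb from the outer into the inner medulla (n = 9 and n = 4). Cxcl1 rose from 0.181 ± 0.478 RPKM to 507 ± 320 (log2 change 8.40 ± 0.84; adjusted p = 3.2e-13), without overlap. Akr1b1, the aldose reductase that makes the osmolyte sorbitol, rose from 60.9 ± 73.9 to 4772 ± 3503 RPKM (7.34 ± 1.51; adjusted p = 0.00082). Cldn2, a cation and water pore, fell from 210 ± 138 to 6.57 ± 7.33 RPKM (-5.11 ± 1.02; adjusted p = 0.00056), and Cldn23 from 223 ± 189 to 49.7 ± 98.8 RPKM. Cldn4, a claudin of tight epithelia, rose from 59.4 ± 104 to 601 ± 473 RPKM. Osmotic response genes rose in 2 of 10 cases, or 7 with 1 lower when adjusted over the list alone (camera adjusted p = 0.057). Of 16 immediate early and heat shock genes 6 rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 1.9e-13, and adjusted p = 0.015 with an estimated correlation). They included Fosb, a transcription factor subunit, from 3.02 ± 6.76 to 221 ± 176 RPKM, and the phosphatase Dusp1, from 34.9 ± 50.6 to 178 ± 154 RPKM. The heat shock genes Hspa1a and Hspa1b, near-identical paralogs between which the assignment of reads is uncertain, reached 514 ± 492 and 176 ± 167 RPKM. Oxidative phosphorylation had 0 of 22 genes called; as a set it was lower (camera adjusted p = 0.00028), but not with an estimated correlation (adjusted p = 0.25). By limma 300 genes passed, 295 higher and 5 lower in LDLIM, 48 of them without overlap (0.28% of all tested genes by chance). All genes moved by a median of 0.59. The count was 137 after quantile normalization, 97 with detected genes as a covariate, 128 without libraries under 2500 genes, 6 with both groups alone and 513 with the replicate number as a block. Leaving out LDLIM 1, 2, 3 or 4 gave 162, 213, 159 or 590. With both groups alone the calls of Cldn2, Cldn4, Cldn23, Dusp1, Hspa1a and Hspa1b ended. Those of Cldn4 and Dusp1 also ended under the covariate, after quantile normalization, without libraries under 2500 genes and without LDLIM 1, 2 or 3, and that of Dusp1 with a pseudocount of 0.1 and in the second table. The call of Cldn23 ended without LDLIM 1, 2 or 3, that of Hspa1a under the covariate and without LDLIM 1 or 2, and those of Hspa1a and Hspa1b without libraries under 2500 genes.

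LDLIM and tAL stand on either side of the bend of the long loop (n = 4 and n = 7). Aqp1 fell from 3629 ± 1467 to 1439 ± 2309 RPKM (log2 change -6.03 ± 1.26; adjusted p = 0.0026). The tAL median was 7.88 RPKM, so a few libraries carried its mean. Without overlap, the matrix protein Egfl6 fell from 115 ± 9.22 to 11.8 ± 23.5 RPKM, the epithelial transcription factor Ehf from 150 ± 39.3 to 23.4 ± 31.0 RPKM, and the actin-binding Enc1 from 40.5 ± 18.3 to 1.68 ± 2.84 RPKM (-4.47 ± 0.77; adjusted p = 7.1e-05). Fscn1, an actin bundler, was listed at 0 in every LDLIM library and averaged 5.32 ± 7.08 RPKM in tAL. In the thin limb list Aqp1 was the only call of 14 genes, with 2 lower when adjusted over the list alone (camera adjusted p = 0.40). Endothelial markers, with 0 of 12 called and 2 higher when adjusted over the list alone, were higher in tAL as a set (camera adjusted p = 1.1e-08, and adjusted p = 0.049 with an estimated correlation). Over all genes 84 passed, 13 higher and 71 lower in tAL, 17 without overlap (0.606% of all tested genes by chance). That share counts genes called or not, so it cannot be set against the 17 called genes. The median moved by -0.17. The share higher was 40% of 75 genes after quantile normalization, 37.2% with the covariate and 26.9% without libraries under 2500 genes. With both groups alone 2 genes passed, and of the genes named here only Aqp1 kept its call. Without LDLIM 1 the count was 53 and without LDLIM 4 it was 188. The calls of Egfl6 and Ehf also ended without LDLIM 1 and with a pseudocount of 0.1, and that of Ehf without LDLIM 2.

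mTAL and cTAL compare the medullary and cortical parts of the thick ascending limb (n = 7 each). Pth1r, the parathyroid hormone receptor, rose from 1.98 ± 2.71 to 146 ± 98.1 RPKM (log2 change 5.37 ± 0.90; adjusted p = 2.0e-05), and Casr, the calcium-sensing receptor, from 18.3 ± 23.8 to 308 ± 190 RPKM (4.58 ± 0.70; adjusted p = 2.5e-06). Cldn16, which forms the paracellular magnesium path, rose from 30.7 ± 59.2 to 142 ± 31.4 RPKM. Divalent cation transport rose in 4 of 16 genes and fell in 0, with 6 higher when adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.018 with an estimated correlation). The thick ascending limb list also had 4 of 21 genes higher, 6 when adjusted over the list alone (camera adjusted p = 6.2e-05, but adjusted p = 0.061 with an estimated correlation). One was Ptgs2, from 0.0009 ± 0.0024 to 49.0 ± 86.4 RPKM. The kinase gene Wnk1, of the distal convoluted tubule list, rose from 9.32 ± 19.5 to 79.0 ± 72.5 RPKM. In that list 1 of 12 genes passed, 2 when adjusted over the list alone (camera adjusted p = 0.0043, but adjusted p = 0.093 with an estimated correlation). Without overlap, Ly6i rose from 24.6 ± 25.3 to 979 ± 809 RPKM and Ush1c, a scaffold protein, from 0.0379 ± 0.0810 to 38.9 ± 36.5 RPKM. The 4 genes lower in cTAL, chosen after their values were seen, were the chaperone Cryab (14.2 ± 21.8 against 137 ± 124 RPKM), the phosphatase inhibitor Ppp1r1b (4.43 ± 4.57 against 38.3 ± 46.9), Igf1 (1.77 ± 1.57 against 14.4 ± 15.2) and Matn1 (0.429 ± 0.603 against 18.0 ± 26.4). Leukocyte markers were higher in cTAL (1 of 12 genes, 5 when adjusted over the list alone; camera adjusted p = 6.2e-05, but adjusted p = 0.061 with an estimated correlation). C1qa was at 28.7 ± 23.7 against 0.880 ± 2.3 RPKM. Immediate early genes, 0 of 16 called, were lower as a set (camera adjusted p = 2.5e-07, but adjusted p = 0.061 with an estimated correlation). Oxidative phosphorylation, 0 of 22 called, was lower by camera (adjusted p = 0.0020, but adjusted p = 0.17 with an estimated correlation) although its median was 0.03, since the median of all genes moved by 0.55. In total 114 genes passed, 110 higher and 4 lower in cTAL, 11 without overlap (0.0583% of all tested genes by chance). Quantile normalization gave 59 with 83.1% higher, the covariate 56, and both groups alone 52, while a pseudocount of 0.1 gave 193. The calls of Cldn16, Wnk1, Cryab and Ppp1r1b ended without libraries under 2500 genes. Those of Ppp1r1b and Matn1 ended with a pseudocount of 0.1, those of Ppp1r1b, Matn1 and Igf1 with both groups alone, those of Ppp1r1b and C1qa under the covariate, and that of Ppp1r1b in the second table.

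DCT and CNT mark the passage from the distal convoluted to the connecting tubule (n = 8 and n = 6). Slc12a3 fell from 267 ± 122 to 0.392 ± 0.877 RPKM (log2 change -7.50 ± 0.50; adjusted p = 1.3e-24), Umod from 710 ± 572 to 3.98 ± 6.91 RPKM and the phosphatase inhibitor Ppp1r1a from 254 ± 116 to 0.345 ± 0.770 RPKM, all without overlap. Aqp2 rose from 149 ± 252 to 4680 ± 3518 RPKM (7.28 ± 1.15; adjusted p = 1.5e-06). Slc26a4, the chloride bicarbonate exchanger pendrin of type B intercalated cells, rose from 3.63 ± 7.70 to 237 ± 201 RPKM (6.20 ± 0.71; adjusted p = 3.8e-11), without overlap. Intercalated cell markers rose in 14 of 20 genes and fell in 0, with 16 higher when adjusted over the list alone (camera adjusted p = 1.5e-45, and adjusted p = 2.7e-08 with an estimated correlation). The proton pump subunit Atp6v1g3 rose from 17.0 ± 28.6 to 646 ± 370 RPKM. Principal cell markers rose in 9 of 17 genes, 11 when adjusted over the list alone (camera adjusted p = 6.8e-24, and adjusted p = 1.3e-07 with an estimated correlation). The sodium channel subunit Scnn1g rose from 0.367 ± 0.564 to 56.7 ± 48.8 RPKM. Of 12 genes of the distal convoluted tubule list 6 fell and 0 rose, 8 when adjusted over the list alone (camera adjusted p = 1.2e-24, and adjusted p = 6.3e-09 with an estimated correlation). The connecting tubule list had 4 of 11 genes higher and 1 lower, Slc12a3, or 6 and 1 when adjusted over the list alone (camera adjusted p = 1.4e-06, and adjusted p = 0.00092 with an estimated correlation). Calb1, the calcium carrier calbindin, rose from 356 ± 293 to 4727 ± 3488 RPKM without overlap (3.77 ± 1.09; adjusted p = 0.039), a call lost with a pseudocount of 0.1, in the second table and without libraries under 2500 genes. Leukocyte markers were lower in CNT (2 of 12 genes, 9 when adjusted over the list alone; camera adjusted p = 6.7e-09, and adjusted p = 0.0026 with an estimated correlation). C1qa was at 0.148 ± 0.260 against 43.9 ± 36.6 RPKM. Endothelial markers, with 0 of 12 called and 3 lower when adjusted over the list alone, were lower as a set (camera adjusted p = 6.8e-05, but adjusted p = 0.092 with an estimated correlation). Of all genes, 238 passed, 98 higher and 140 lower in CNT, 44 without overlap (0.0666% of all tested genes by chance). With both groups alone 136 passed.

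CNT and CCD lie in the cortex, where connecting tubules drain into collecting ducts (n = 6 and n = 11). Calb1 fell from 4727 ± 3488 to 424 ± 596 RPKM (log2 change -5.74 ± 1.03; adjusted p = 0.00064), Klk1, the protease kallikrein, from 357 ± 181 to 129 ± 400 RPKM (-5.51 ± 0.96; adjusted p = 0.00041) and Trpv5 from 8.52 ± 10.2 to 0.753 ± 1.97 RPKM (-1.87 ± 0.31; adjusted p = 0.00023). These are the 3 called of 11 connecting tubule genes, 4 being lower when adjusted over the list alone (camera adjusted p = 1.1e-11, and adjusted p = 8.3e-06 with an estimated correlation). The median of the list was -0.04 and its mean -1.16. Divalent cation transport had 2 of 16 genes lower, Calb1 and Trpv5, and 3 when adjusted over the list alone (camera adjusted p = 3.6e-10, and adjusted p = 8.3e-05 with an estimated correlation). Principal cell markers had 0 of 17 called and were higher in CCD as a set (camera adjusted p = 0.033), but not with an estimated correlation (adjusted p = 0.37). Immediate early genes had 0 of 16 called and were higher as a set (camera adjusted p = 0.00074, but adjusted p = 0.37 with an estimated correlation). Only 8 genes passed, and the other 5 were chosen after their values were seen. The defensin gene Defb9 (68.6 ± 124 in CNT against 6.29 ± 13.4 RPKM in CCD), Zbtb41 (15.9 ± 25.4 against 0.0904 ± 0.220) and Ppm1n (4.18 ± 6.43 against 0.0442 ± 0.0990) were lower in CCD. Dnaaf1 (4.64 ± 9.19 against 35.6 ± 32.9) and the homeobox gene Hmx3 (3.72 ± 4.91 against 14.8 ± 22.7) were higher. None of the 8 was free of overlap between libraries, and the median of all genes moved by 0.31. A pseudocount of 0.1 left 2 genes and ended the calls of Calb1 and the 5 genes just named. Both groups alone gave 2, Calb1 and Klk1, the fit without libraries under 2500 genes 5, and quantile normalization 15, 6.7% of them higher. Each of the 5 lost its call under at least 1 further alternative.

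CCD and OMCD follow the collecting duct out of the cortex (n = 11 and n = 7). Hmx2, a homeobox gene, fell from 223 ± 91.1 to 11.3 ± 18.6 RPKM (log2 change -5.65 ± 0.54; adjusted p = 3.2e-14), without overlap. All 5 tested markers of type B intercalated cells, which secrete bicarbonate, were lower in OMCD, also when adjusted over the list alone (camera adjusted p = 3.9e-24, and adjusted p = 7.4e-08 with an estimated correlation). They included Slc26a4, from 290 ± 232 to 22.9 ± 27.4 RPKM, and the receptor gene Insrr, from 135 ± 146 to 4.65 ± 8.83 RPKM. Of 6 type A markers, from the cells that secrete acid, 1 rose and 0 fell, or 3 and 2 when adjusted over the list alone (camera adjusted p = 3.3e-06, and adjusted p = 0.0054 with an estimated correlation). The riser was the anion exchanger Slc26a7, from 0.0949 ± 0.270 to 16.1 ± 22.8 RPKM. Of 17 principal cell markers 1 rose, the water channel Aqp4, from 27.6 ± 25.6 to 89.4 ± 50.8 RPKM. The list was higher by camera (adjusted p = 0.0050, but adjusted p = 0.21 with an estimated correlation) although its median was -0.15 and its mean -0.02. Dnase1, a deoxyribonuclease, rose from 43.4 ± 35.2 to 451 ± 321 RPKM and Casr fell from 14.5 ± 9.90 to 0.199 ± 0.196 RPKM, both without overlap. Igfbp5 fell from 113 ± 63.2 to 6.70 ± 10.9 RPKM in this table but was not called in the second table. In total 144 genes passed, 9 higher and 135 lower in OMCD, 8 without overlap (0.00628% of all tested genes by chance). All genes moved by a median of -0.59. Quantile normalization gave 47 genes with 55.3% higher and ended the call of Casr. The covariate gave 57 with 26.3% higher, and both groups alone gave 72. The call of Aqp4 ended with both groups alone, with a pseudocount of 0.1 and with the replicate block.

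OMCD and IMCD compare the outer and inner medullary collecting duct (n = 7 and n = 8). S100a4 rose from 51.9 ± 89.3 to 6411 ± 4334 RPKM (log2 change 9.37 ± 1.09; adjusted p = 1.7e-11), Slc14a2, the urea transporter of the terminal duct, from 0.0780 ± 0.186 to 388 ± 283 RPKM (8.22 ± 0.73; adjusted p = 6.8e-17), and Akr1b1 from 134 ± 138 to 8593 ± 5710 RPKM, all without overlap. Atp6v1g3 fell from 852 ± 214 to 12.1 ± 21.2 RPKM (-7.76 ± 0.81; adjusted p = 2.2e-13) and Hsd11b2, which shields the mineralocorticoid receptor from glucocorticoids, from 987 ± 296 to 16.4 ± 21.7 RPKM, again without overlap. Intercalated cell markers fell in 16 of 20 genes and rose in 0, with 19 lower when adjusted over the list alone (camera adjusted p = 2.0e-64, and adjusted p = 1.8e-10 with an estimated correlation). Aqp6, their intracellular water channel, fell from 365 ± 221 to 4.62 ± 8.28 RPKM, a call lost in the second table. Of 17 principal cell markers 7 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 3.9e-11, and adjusted p = 0.00062 with an estimated correlation). The sodium channel subunit Scnn1a fell from 45 ± 42.9 to 0.717 ± 1.27 RPKM and the potassium channel Kcnj1 from 23.9 ± 22 to 0.0415 ± 0.113 RPKM. Aqp4 rose from 89.4 ± 50.8 to 364 ± 212 RPKM, a call lost under 5 alternatives. Osmotic response genes rose in 4 of 10 cases, 6 when adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.0025 with an estimated correlation). The inositol transporter Slc5a3 rose from 1.44 ± 1.49 to 68.5 ± 71.9 RPKM. Oxidative phosphorylation fell in 3 of 22 genes, 4 when adjusted over the list alone (camera adjusted p = 7.2e-09, and adjusted p = 0.012 with an estimated correlation). Cox4i1 fell from 2822 ± 1034 to 877 ± 566 RPKM. In the inner medullary collecting duct list 3 of 12 genes rose, also when adjusted over the list alone (camera adjusted p = 0.087). Immediate early and heat shock genes rose in 7 of 16 cases, 10 when adjusted over the list alone (camera adjusted p = 1.3e-05, but adjusted p = 0.115 with an estimated correlation). Dusp1 rose from 13.5 ± 34.7 to 68.3 ± 43.1 RPKM. Over all genes 828 passed, 718 higher and 110 lower in IMCD, 81 without overlap (0.0311% of all tested genes by chance). The median moved by 0.55. Quantile normalization gave 566 with 58.8% higher, the covariate 564 with 66.1% higher, and both groups alone 371.

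The labels state digestion at 37 °C for 25 min for cortex, 50 min for outer medulla and 90 min for inner medulla, so digestion time and kidney zone change together in the comparisons that cross zones. The mean log2 level of the 16 immediate early and heat shock genes was 5.81 in tAL, 5.81 in IMCD and 6.87 in LDLIM of the inner medulla. It was 0.51 in S1, 0.785 in S2, 1.46 in S3, 2.19 in DCT, 2.33 in cTAL and 2.64 in CNT. CCD, from the cortex, was at 4.01, above SDL (3.71), LDLOM (3.29), OMCD (3.17) and mTAL (2.97) of the outer medulla.

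**Figure D3:**
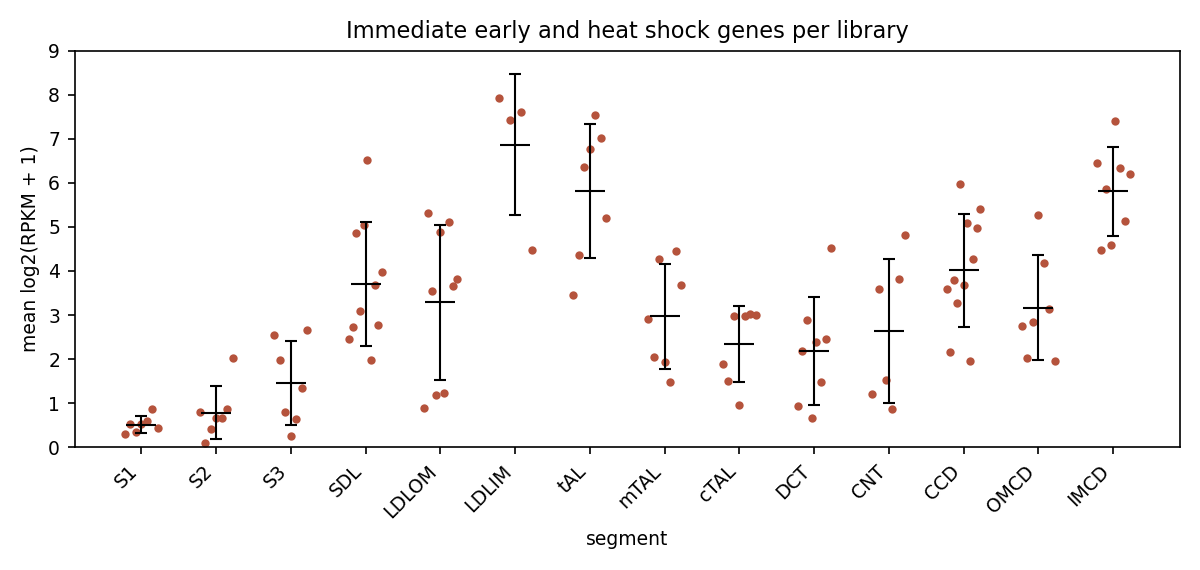
Mean log2(RPKM + 1) of 16 immediate early and heat shock genes (vertical axis) in each library (points) of the 14 segments (horizontal axis), with the mean and SD of each segment as bars. LDLIM, tAL and IMCD have the highest means, 6.87, 5.81 and 5.81, and S1 the lowest, 0.51.

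Glomerulus and S1 compare the filter with the first tubule part (n = 5 and n = 7). The glomeruli were submitted later than the tubules, and their labels give no weight or digestion time. Batch and tissue thus cannot be told apart in this comparison. Mgp, a calcification inhibitor, averaged 4812 ± 852 RPKM in glomeruli and 9.17 ± 15.2 in S1 (log2 change -10.05 ± 1.46; adjusted p = 7.7e-09), without overlap. Kap, the androgen-regulated kidney protein, was higher in S1 (3275 ± 3612 against 3.07 ± 3.16 RPKM; log2 change 9.14 ± 1.48; adjusted p = 1.9e-07), as was Glyat, a glycine conjugating enzyme (1685 ± 1256 against 3.27 ± 4.08 RPKM). All 13 podocyte markers were higher in glomeruli, also when adjusted over the list alone (camera adjusted p = 1.6e-20, and adjusted p = 2.7e-10 with an estimated correlation). The 13 endothelial markers were all higher in glomeruli as well, such as the receptor Tie1 at 94.7 ± 31.2 against 8.80 ± 14.3 RPKM (13 when adjusted over the list alone; camera adjusted p = 4.7e-08, and adjusted p = 0.020 with an estimated correlation). Mesangial and stromal markers were higher in 6 of 10 cases, also when adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.0014 with an estimated correlation), with the growth factor receptor Pdgfrb at 39.0 ± 11.3 against 0.0027 ± 0.0072 RPKM. Proximal reabsorption was higher in S1 in 9 of 20 genes, also when adjusted over the list alone (camera adjusted p = 2.1e-12, and adjusted p = 5.0e-05 with an estimated correlation), with Slc34a1 at 1504 ± 2115 against 9.96 ± 8.39 RPKM. Oxidative phosphorylation was higher in S1 in 4 of 22 genes, also when adjusted over the list alone (camera adjusted p = 2.8e-06, and adjusted p = 0.031 with an estimated correlation). Leukocyte markers were higher in glomeruli in 8 of 12 cases, 9 when adjusted over the list alone (camera adjusted p = 0.40). Immediate early genes were higher there in 15 of 16, 16 when adjusted over the list alone (camera adjusted p = 0.00053, but adjusted p = 0.17 with an estimated correlation). In total 5027 of 11456 genes passed, 373 higher and 4654 lower in S1. Of these, 3137 were without overlap (0.253% of all tested genes by chance). The median over all genes was -1.60. Quantile normalization gave 2087 with 46.7% higher in S1, and the covariate 2233 with 24.0% higher. The glomerulus columns may use other gene models for some genes, which the tables used here cannot settle as a whole. Mrpl1 averaged 8771 ± 2717 RPKM in S1 against 0.830 ± 0.266 in glomeruli. Over the tubule libraries Mrpl1 averaged 12291 RPKM in the main table but 0.733 in the second, so its S1 level depends on the gene model. Its glomerulus level was near that of tubules in the second table. Myl6l goes the other way. It averaged 19116 RPKM over tubules in the main table and 58.6 in the second, yet was the highest gene in all 5 glomerulus libraries. Atn1, Ewsr1 and Tspan4 averaged 6632 ± 229, 6239 ± 734 and 723 ± 148 RPKM in glomeruli against at most 0.0751 ± 0.149 in S1.

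Water load asks which genes change in collecting ducts that escape from vasopressin. Rats 5 weeks old received the vasopressin V2 agonist ddAVP at 5 ng per h from minipumps, with 50 mL of water per day in gelled food (water load, n = 4) or 25 mL (control, n = 4), and CCD were taken after 4 days per the labels. The column names of the table start with D2, which would disagree with the 4 days if it means day 2, so the day of these values is uncertain. Aqp2 averaged 7534 ± 2400 RPKM with water load and 14510 ± 3872 in controls, 1.94-fold lower (log2 difference -0.96; exact two-sided permutation p = 0.0286, the smallest that 70 splits allow). Aqp3, the basolateral water channel, was at 424 ± 189 against 1416 ± 428 RPKM (-1.79 ± 0.36) and was not called (adjusted p = 0.076), though the libraries did not overlap. Tubb5, a tubulin, rose from 60.4 ± 11.0 to 231 ± 51.2 RPKM (1.91 ± 0.27; adjusted p = 0.021), the histone chaperone Asf1b from 0.674 ± 1.11 to 15.2 ± 6.18 RPKM. The mitotic ubiquitin enzyme Ube2c rose from 4.93 ± 6.20 to 39.9 ± 1.69 RPKM and the cell cycle transcription factor E2f1 from 0.0628 ± 0.0544 to 4.02 ± 0.954 RPKM. The replication factor Cdc45 (5.62 ± 1.94 against 0.273 ± 0.356), the kinetochore protein Knstrn (17.1 ± 8.79 against 1.08 ± 1.83), Ube2t (7.51 ± 6.03 against 0.0282 ± 0.0032) and Mlf1 (6.56 ± 4.70 against 0.0227 ± 0.0269) were also higher. The Wnt antagonist Sfrp2 fell from 33.3 ± 11.7 to 2.37 ± 2.26 RPKM (-3.47 ± 0.48; adjusted p = 0.021), the phosphatidate phosphatase Lpin2 from 350 ± 183 to 60.5 ± 23.4 RPKM. Also lower were Eva1b, from 226 ± 84.0 to 58.0 ± 20.8, Snn from 492.8 ± 29.4 to 191.7 ± 24.7 and Vasn, which binds TGF-beta, from 72.3 ± 34.0 to 16.2 ± 1.07 RPKM. These 13 genes, 8 higher and 5 lower, are all that limma called of 8492. Each had 4 of 4 libraries beyond all those of the other group. By chance 2.86% of all tested genes do so, but these 13 were called from the same libraries. Their lack of overlap is thus no further support.

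Cell cycle genes were not called one by one over all genes (0 of 20 by limma, with 632 of 8492 genes at an unadjusted p under 0.05). When adjusted over the list alone 16 of 20 were higher with water load and 0 lower (camera adjusted p = 1.2e-19, and adjusted p = 0.0069 with an estimated correlation). The replication helicase subunit Mcm3 was at 11.4 ± 3.92 against 1.71 ± 2.13 RPKM and the cyclin Ccnb2 at 29.4 ± 13.1 against 6.72 ± 5.60 RPKM. Vasopressin signalling was lower as a set (1 of 15 genes when adjusted over the list alone, Aqp3; camera adjusted p = 6.7e-05, and adjusted p = 0.046 with an estimated correlation). So were principal cell markers (1 of 16, again Aqp3; camera adjusted p = 0.0013, and adjusted p = 0.046 with an estimated correlation). Cholesterol synthesis was higher as a set, with 0 of 17 genes when adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.046 with an estimated correlation). Oxidative phosphorylation was higher (1 of 22 when adjusted over the list alone; camera adjusted p = 3.8e-08, but adjusted p = 0.057 with an estimated correlation). So was glycolysis (2 of 14 higher and 1 lower; camera adjusted p = 0.0051, but adjusted p = 0.15 with an estimated correlation), with Pgk1 at 1133 ± 208 against 509 ± 162 RPKM. Immediate early genes were lower (2 of 15 when adjusted over the list alone; camera adjusted p = 1.1e-07, but adjusted p = 0.10 with an estimated correlation), such as Jun at 29.8 ± 5.30 against 81.8 ± 31.5 RPKM. Libraries with the same number in both groups resembled each other, with correlations of 0.209 to 0.313 between their residuals, although the labels give each number a rat of its own. With the number as a block 29 genes passed, 48.3% of them higher. The camera adjusted p with an estimated correlation became 0.053 for cell cycle, 0.114 for cholesterol synthesis and principal cell markers and 0.086 for vasopressin signalling. By fry without the block, the adjusted p was 0.0014 for cell cycle and cholesterol synthesis, 0.014 for vasopressin signalling and 0.025 for principal cell markers. It was also 0.025 for oxidative phosphorylation and glycolysis, and 0.066 for immediate early genes. With the block, the fry adjusted p was 0.013 for cell cycle, cholesterol synthesis and oxidative phosphorylation, and 0.0035 for vasopressin signalling. It was 0.063 for principal cell markers, 0.028 for glycolysis and 0.025 for immediate early genes. With the preset correlation, the blocked camera adjusted p was 2.4e-18 for cell cycle and 0.0015 for cholesterol synthesis. It was 3.5e-05 for vasopressin signalling and 0.00062 for principal cell markers. The tests thus disagree on each of these lists. Aqp2 gave a paired exact p of 0.125. A pseudocount of 0.1 and dropping the filter each gave 0 genes. Quantile normalization gave 9 with 44.4% higher, and leaving out 1 of the libraries 0 to 7.

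**Figure D4:**
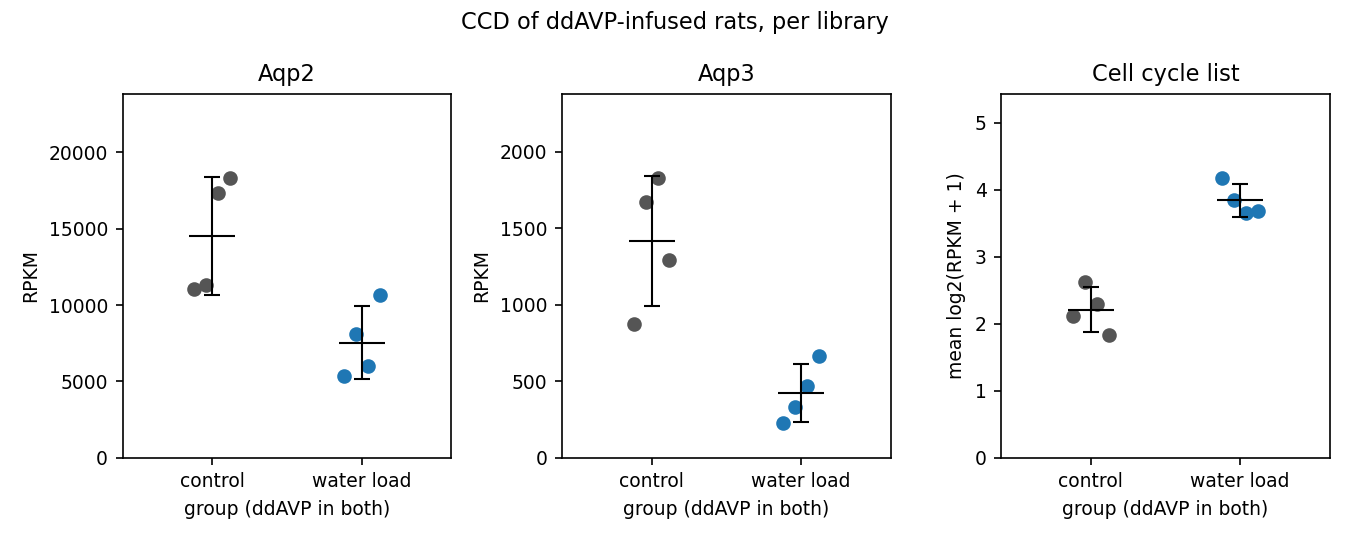
Aqp2 and Aqp3 (RPKM) and the mean log2(RPKM + 1) of the cell cycle list (vertical axes) in CCD of ddAVP-infused rats with control water intake or water load (horizontal axis); points are libraries, bars mean and SD (n = 4 each). Every water-load library is below every control library for Aqp2 and Aqp3 and above every control library for the cell cycle list.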

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

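Chosen only after the result was seen were the tests of digestion, of sequencing depth, of detection of low genes and of other cell types. The split counts, the detected-genes covariate for immediate early genes in IMCD against OMCD and the test of a few dominant genes were planned beforehand. The same covariate in LDLIM against LDLOM was not among the planned tests.

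Immediate early and heat shock genes were higher in the inner medulla, by 2.64 ± 0.567 (SE) on the log2 scale in IMCD against OMCD (n = 8 and n = 7, exact permutation p = 0.0014). The same list was higher by 3.58 ± 1.03 in LDLIM against LDLOM (n = 4 and n = 9, exact p = 0.00979). With the number of detected genes as a covariate the IMCD difference was 1.93 ± 0.543 and the LDLIM difference 1.86 ± 0.552, which argues against unequal detection as the whole cause, although it may account for a part. The longer digestion of the inner medulla cannot be told apart from its position, because all inner medullary tubules were digested for 90 min and none of the others. Both digestion and a biological difference between the zones may contribute, the latter untested.

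The number of detected genes differed widely within segments. Its Spearman rho with relative depth within groups was -0.085 (permutation p = 0.41), and -0.204 among the 54 libraries whose references all agree within tolerance. Pearson r was -0.117 (permutation p = 0.27), or -0.098 without the 2 libraries farthest from the median. Detected genes thus did not rise with the estimated depth. Depths are known only up to whole-number factors, and in a library as few as 5.3% of the low ratios were whole. Errors in depth weaken such a relation, so it cannot decide whether depth was a source. With the share of the 10 highest genes, rho was -0.172 (permutation p = 0.085, adjusted over both relations 0.17; r -0.114, p = 0.40, or -0.155 without 2 libraries), so a few genes taking most of the values cannot be told apart from other sources, since this relation is too weak to decide. The amount of RNA per dissected tubule was not tested.

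Cell cycle genes were higher with water load, by 1.63 in the list mean (exact permutation p = 0.0286, the smallest possible) and in 4 of 4 pairs of libraries with the same number (paired exact p = 0.125). The median change of 1.61 lay at percentile 100 of 10000 random lists matched on expression, the central 95% of which ended at 0.32, which argues against a general gain in detection of low genes. Summed RPKM of leukocyte, endothelial and stromal markers rose by 27.1 ± 286 against 385.5 ± 147 for the cell cycle list, a difference of -358.5 ± 273, so proliferating cells of other types carried along cannot be told apart from tubule cells at this spread. More cycling of tubule cells with water load may be a biological explanation and was not tested.

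Other values stood apart from the rest of their group. In a test for single distant samples over 116 groups and measures 15 did so, where chance gives about 1 in 20. LDLOM 7 had 8574 detected genes (others 1438 to 4983) and mTAL 7 had 6760 (others 1795 to 3915). The endothelial list mean was 0.01 in cTAL 4 (others 1.41 to 2.16). The immediate early list mean was 5.53 in water load 3 (others 4.84 to 4.95), 4.49 in LDLIM 4 (others 7.44 to 7.93) and 2.02 in S2 7 (others 0.10 to 0.88). The leukocyte list mean was 1.24 in OMCD 5 (others 0.13 to 0.34) and 4.39 in SDL 5 (others 0.20 to 2.37), and the stromal list mean 0.28 in OMCD 6 (others 0.00 to 0.02). The podocyte list mean was 1.34 in control 3 of the water-load experiment (others 0.95 to 1.00) and 1.17 in S1 5 (others 0.01 to 0.40). The 10 highest genes held 33.76% of the RPKM sum in LDLIM 4 (others 25.04 to 26.42%), 64.65% in LDLOM 8 (others 21.64 to 28.73%), 42.84% in S1 6 (others 22.78 to 30.32%) and 38.39% in S2 6 (others 20.50 to 27.49%).

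Redrawn group labels tested whether chance can be excluded, with the real split included in each count. It can for S2 against S3 (2 of 100 splits gave as many; 98 genes, highest other 118), mTAL against cTAL (1 of 100; 114, highest other 81), DCT against CNT (1 of 100; 238, highest other 99), CCD against OMCD (1 of 100; 144, highest other 44), OMCD against IMCD (2 of 100; 828, highest other 1150), Glomerulus against S1 (1 of 100; 5027, highest other 2233) and selective genes (1 of 100; 132, highest other 10). It cannot for S1 against S2 (8 of 100; 66, highest other 110), SDL against LDLOM (28 of 100; 17, highest other 672), LDLOM against LDLIM (5 of 100; 300, highest other 1533), LDLIM against tAL (27 of 100; 84, highest other 794), CNT against CCD (39 of 100; 8, highest other 158) and water load (2 of 35; 13, highest other 378). These shares were not adjusted over the comparisons, and a rare count does not tell tissue apart from zone, digestion or batch. The replicates may also be technical, so other splits may not be fair draws. For selective genes the labels of all 105 libraries were redrawn at once, which asks only whether any segments differ. Splits that call several times the real count in SDL against LDLOM, LDLOM against LDLIM, LDLIM against tAL, CNT against CCD and water load point to a structure of the samples other than the groups. For water load, among the 8 splits that part all 4 pairs of equal numbers the highest other was 0, and the 378 came from 1 of the 3 splits that keep all 4 pairs together. That split set numbers 1 and 2 of both groups against numbers 3 and 4. The other 2 of these 3 called 0 genes, as did all further splits that keep a pair. The structure thus followed the replicate numbers, with 1 and 2 apart from 3 and 4, and its cause was not tested. The blocked fit called 29 genes.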

How the results depend on the processing

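Results with all transcripts, with the covariate, without the libraries under 2500 genes and, for glomeruli, with only genes within 4-fold between the tables were chosen only after the result was seen; the other alternatives were planned. No named gene, list or selective gene reversed its direction, but the majority direction of called genes did in some comparisons. In CCD against OMCD 6.2% were higher, and 55.3% after quantile normalization; in DCT against CNT 41.2% and 50.2%. For water load 61.5% were higher, but 44.4% after quantile normalization, 48.3% with the replicate block, 16.7% without control 4 and 0 of 1 without water load 2. Among values of named genes 1335 kept their direction and stayed called or uncalled as before, 317 lost the call and 9 gained one. Lists were counted by camera with the preset correlation alone. Of these, 441 stayed on the same side of an adjusted p of 0.05 and 12 rose above it. The 12 were of the thick ascending limb, distal convoluted tubule and oxidative phosphorylation lists in mTAL against cTAL, and of principal cell markers in CNT against CCD and CCD against OMCD. The estimated correlation was not counted, under which the replicate block moved the camera adjusted p for cell cycle from 0.0069 to 0.053. For selective genes 244 kept the call and 38 lost it. The total of selective genes stayed within 1.5 times 132, while counts for single segments moved further in 29 cases and stayed within that range in 139.

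Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested except where noted. A fit of both groups alone leaves fewer libraries to estimate the spread. It also tests fewer genes, such as 6545 instead of 11078 for S1 against S2. That fit gave 6 for S1 against S2, 10 for S2 against S3, 1 for SDL against LDLOM, 6 for LDLOM against LDLIM and 2 for LDLIM against tAL. It gave 52 for mTAL against cTAL, 136 for DCT against CNT, 2 for CNT against CCD, 72 for CCD against OMCD and 371 for OMCD against IMCD. A pseudocount of 0.1 gave 38 for S1 against S2, 10 for SDL against LDLOM, 193 for mTAL against cTAL, 2 for CNT against CCD and 0 for water load. Quantile normalization gave 137 for LDLOM against LDLIM, 59 for mTAL against cTAL, 15 for CNT against CCD, 47 for CCD against OMCD and 2087 for Glomerulus against S1. The covariate gave 97 for LDLOM against LDLIM, 56 for mTAL against cTAL, 57 for CCD against OMCD and 2233 for Glomerulus against S1. Without libraries under 2500 genes, the counts were 37 for S1 against S2, 128 for LDLOM against LDLIM and 5 for CNT against CCD. The replicate block gave 513 for LDLOM against LDLIM and 29 for water load. No filter gave 0 and array weights 25 for water load.

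Leaving out 1 library gave 159 (LDLIM 3) to 590 (LDLIM 4) genes for LDLOM against LDLIM, with 162 without LDLIM 1, and 53 (LDLIM 1) to 188 (LDLIM 4) for LDLIM against tAL. For water load it gave 0 to 7: 7, 7, 5 and 6 without control 1, 2, 3 and 4, and 0, 1, 0 and 0 without water load 1, 2, 3 and 4. Aqp2 was lower by log2 in each of these, from -0.81 to -1.14. The exact p was 0.0571 without control 1, 2, 3 or 4 or water load 1 and 0.0286 without water load 2, 3 or 4. With the replicate block, Aqp2 gave -0.96 with a paired exact p of 0.125, the smallest that 4 pairs allow. After quantile normalization its difference was 0 because Aqp2 is the highest gene of every library, which makes that test void. The second table could not be run for Glomerulus against S1. Depth is known only as a ratio between libraries, so it sets no limit of detection.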

Other observations

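Transcription factors, G protein-coupled receptors and claudins, 3 lists fixed before the data were examined, were compared over all 14 segments by limma; no test of this part was chosen after the result was seen. Of 33 tested transcription factors 29 differed between segments, of 23 receptors 19 and of 17 claudins 14, out of 4595 of 11078 genes. Hnf4a, a nuclear receptor of the proximal tubule, averaged 20.4 ± 16.8 RPKM in S1, 44.3 ± 51.2 in S2 and 34.9 ± 28.9 in S3 (n = 7 each; adjusted p over all segments = 3.4e-20). Foxi1, a regulator of intercalated cells, averaged 73.2 ± 58.3 RPKM in CNT (n = 6), 110.5 ± 76.0 in CCD (n = 11) and 122 ± 124 in OMCD (n = 7) (adjusted p = 2.3e-26). Gata3 averaged 91.3 ± 91.2 RPKM in CNT, 97.0 ± 57.0 in CCD, 96.2 ± 76.3 in OMCD and 63.5 ± 41.7 in IMCD (n = 8; adjusted p = 1.9e-30). Pax8 was at 338 ± 226 RPKM in SDL (n = 10) and 302 ± 155 in LDLIM (n = 4; adjusted p = 3.8e-07). Elf3 reached 591 ± 386 RPKM in IMCD and 351 ± 93.2 in LDLIM (adjusted p = 1.5e-08). Only 2 of the transcription factors were selective, Sall3 for DCT and Elf5 for IMCD.

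Among receptors, Avpr2, the vasopressin V2 receptor, averaged 194 ± 137 RPKM in CNT, 387 ± 173 in CCD, 487.5 ± 214 in OMCD and 406 ± 198 in IMCD (adjusted p = 1.2e-27). Pth1r was at 145 ± 98.0 RPKM in S1, 264 ± 261 in S2, 80.96 ± 97.53 in S3 and 146 ± 98.1 in cTAL (adjusted p = 2.4e-21). Ptger3, a prostaglandin receptor, was at 103 ± 101 RPKM in DCT and 81.9 ± 54.4 in mTAL (n = 7; adjusted p = 7.9e-14), and Gcgr, the glucagon receptor, at 87.1 ± 120 RPKM in cTAL (adjusted p = 7.8e-08). Cldn10 averaged 273 ± 153 RPKM in mTAL, 203 ± 119 in cTAL and 232 ± 276 in tAL, and Cldn8 143 ± 113 RPKM in CCD.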
